A study of Homo sapiens with 24 samples.

How the data were processed

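MV4-11 cells, a human acute myeloid leukaemia line, were grown without drug, with 100 nM ATRA, with 100 nM of the PI3K and mTOR inhibitor, or with both, for 3, 12 or 24 h. Sample labels name the inhibitor NVP-BEZ238, whereas the treatment protocol and the series design name NVP-BEZ235, and BEZ235 is used here. The control cells are labelled untreated, and no vehicle is named. Per the labels each of the 12 groups has 2 biological replicates, giving 24 Affymetrix Human Gene 1.0 ST arrays (WT PLUS kit). The deposited values are log2 expression values that the authors background corrected, quantile normalized and summarized by RMA, 1 column per array and no centring per gene. The labels also name limma 3.46.0 without its role, and the RMA settings are not given in the sources used here. Values ran from 3.76 to 14.87 and array medians from 7.27 to 7.38, as log2 values of a common scale have. After quantile normalization a change is relative to the other genes of an array, and a change of total RNA per cell would not be seen. Arrays have no read depth, and their precision was read from the replicates.

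Of 32321 probe sets 20546 had gene names, and the 19158 with a single name, covering 18404 genes, were used. Symbols were matched to a table of human genes by gene ID. No coordinates are given, since the array annotation's genome build is not stated in the sources used here. Probe sets above the median of their array on at least 2 arrays were kept, so a kept gene can still be dim in a compared group, and the probe set with the highest mean stood for each gene. This left 11689 genes. A gene that cross-hybridizes or sits near the background of its array has a compressed fold change.

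All 24 arrays were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, 12 residual degrees of freedom and an empirical Bayes prior of 5.93. Each adjusted p in the text is from limma's moderated test or from its gene list test, adjusted by Benjamini-Hochberg within a comparison, with 0.05 as the threshold. Counts at an unadjusted p and the permutation p of the small RNAs are named as such. There were 23 comparisons. At each time they were each drug and the combination against untreated cells, the combination against each drug, and the interaction (combination minus both drugs plus untreated). In addition untreated cells were compared over time, and each effect at 24 h with that at 3 h. SEs are moderated by the same prior.

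Gene lists were written before the data were examined, and the same holds for the groups, comparisons, gene naming and the alternatives unless stated. A list of at least 3 measured genes was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists of a comparison, for 594 tests in the 18 drug and interaction comparisons. This correlation is a choice, and every list value is given beside the test with a correlation estimated from the residuals. A list p asks whether its genes moved more than other genes. Where a list is said not to shift, it did not pass this test, which does not show that its genes stayed unchanged. List counts in the text are of tested genes, which can be fewer than those listed. Tested were 11 of 24 granulocyte maturation, 11 of 25 monocyte and macrophage, 10 of 20 retinoid, and 5 of 10 class II MHC genes. Counts of list members used the adjustment over all genes, and again the list's genes alone. Genes were named by rule. For each drug against untreated and for the interaction these were the 6 highest and 6 lowest passing genes whose arrays do not overlap between groups (4 and 4 for the combination against a single drug). Up to 4 passing members of each list with the largest change, and 17 genes fixed in advance, completed the names. The fixed genes RARA and HOXA9 had no probe set of their own, and mitochondrial-genome genes had none with a single name.

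Alternatives were no filter, a filter at the 70th percentile, the mean of a gene's probe sets, another quantile normalization, a shift of every array to a common median, a variance prior with trend and robust fit, only the arrays of a time point, the replicate number as a block over all arrays or within a time point, limma's fry, the estimated correlation, and leaving out each array in turn. When an array was left out, its lone partner was assumed to vary like the other groups. These fits had no block, so a value without 1 array also carries any difference shared by same-numbered arrays. Protein-coding genes alone, the estimated correlation with a block, and list counts, cell type markers and small RNAs without each array were chosen after seeing the data. The pipeline was tested on simulated data with each gene's observed spread, drawn independently for every gene and array. With 50 genes changed at each size, 2, 19, 46 and 50 were called at log2 changes of 0.25, 0.5, 1 and 2 for ATRA at 24 h, and 0, 7, 39 and 48 for the interaction, with 8 and 6 unchanged genes called. Of 20 random lists 0 were called by camera, and a list of 30 genes shifted by 0.5 was called with either correlation. Without correlation between genes or a shared replicate effect, these simulated calls do not show how camera performs on correlated genes. Probe sets with no single gene name were kept out of the comparisons and counted separately.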

Results

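Gene expression was measured in MV4-11 cells, an established human acute myeloid leukaemia line known to carry a KMT2A::AFF1 fusion and an internal tandem duplication of FLT3. Cells were left untreated or received 100 nM all-trans retinoic acid (ATRA), the ligand of the retinoic acid receptors, 100 nM BEZ235, an inhibitor of PI3K and mTOR kinases, or both. RNA was taken at 3, 12 and 24 h, with 2 biological replicates in each of the 12 groups and 24 arrays in all. Changes of 11689 genes are log2 fold changes ± SE (n = 2 arrays in every group). The SE rests on a single variance per gene over all 12 groups, so it can be too small for groups whose replicates differ most. Replicates correlated with Pearson's r between 0.977 and 0.995 across genes, which are not independent of each other. The SD of their difference ran from 0.145 at 12 h without drug to 0.319 in the 24 h combination. Replicate 1 of that combination had the narrowest spread of values (SD 2.22, the other arrays 2.27 to 2.32). The number of arrays limits the precision, with a median SE of 0.135. Counts of passing genes come from the fit without a block. With the replicate number as a block counts were higher, as given with the other settings below. Unless stated, a named gene kept its call and its value moved by less than 1.5 times when any 1 array of its comparison was left out. Where a single count of a gene list is given, the count adjusted over the list alone was the same.

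**Figure D1:**
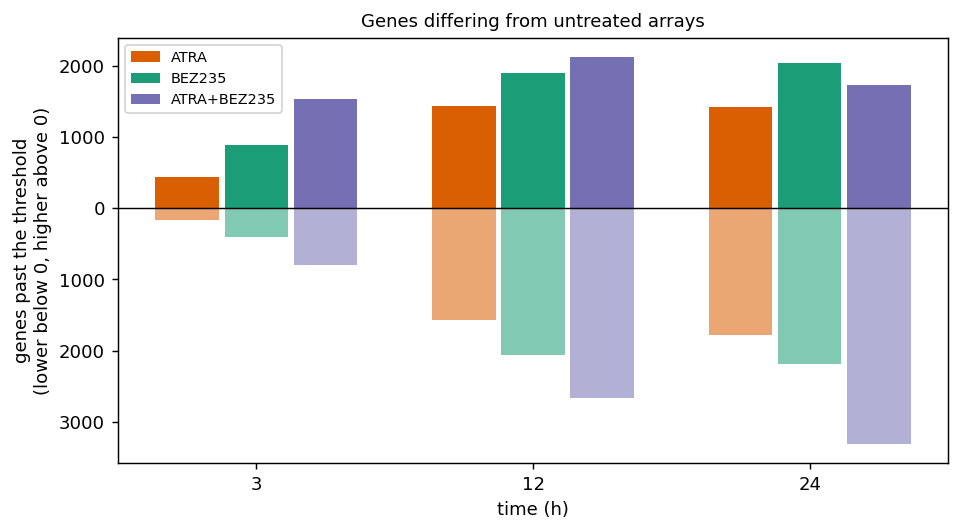
Number of genes past an adjusted p of 0.05 against untreated arrays of the same time, for ATRA, BEZ235 and both at 3, 12 and 24 h, with higher genes above and lower genes below 0. The combination gave 2335, 4790 and 5033 genes, from 1529 higher and 806 lower at 3 h to 1723 higher and 3310 lower at 24 h.

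What ATRA alone changes was read against untreated arrays of the same time. After 3 h CD38, an ectoenzyme and direct retinoic acid target (transcript cluster 8094240), was 11.4-fold higher (3.51 ± 0.18). ITGA6, an integrin subunit, rose by 3.33 ± 0.21, DHRS3, a reductase of retinal, by 3.22 ± 0.14, and TGM2, tissue transglutaminase, by 2.92 ± 0.33. Low values were led by GPR183, an oxysterol receptor (-2.12 ± 0.20), PTGER4, a prostaglandin E2 receptor (-1.78 ± 0.12), and FOSL2, an AP-1 subunit (-1.47 ± 0.12). Of 10 genes of retinoid metabolism and direct retinoic acid targets, 7 rose, among them the retinoic acid hydroxylase CYP26A1 (2.10 ± 0.19), and 0 fell. The median was 1.0 (adjusted p = 7.29e-15, adjusted p = 4.69e-04 with an estimated correlation). Of 13 myeloid transcription factors, 2 rose (3 adjusted over the list alone), with ID1 at 2.38 ± 0.15 and CEBPB at 1.02 ± 0.16. In the same list 4 fell (5 adjusted over the list alone, 1 without untreated replicate 1 and 2 without ATRA replicate 1), with NAB2, a corepressor of EGR proteins, at -0.78 ± 0.11, and the list did not shift (median -0.23, adjusted p = 0.445, adjusted p = 0.952 with an estimated correlation; -0.15 without ATRA replicate 1). MYC fell (-1.27 ± 0.16), and the other 25 of 26 MYC and ribosome biogenesis genes did not pass. Their median was -0.24 (adjusted p = 0.0228, adjusted p = 0.952 with an estimated correlation; -0.15 without untreated replicate 2, -0.08 without ATRA replicate 1 and -0.39 without ATRA replicate 2). Of 13 NF-kB and inflammatory mediators, 4 rose (2 without untreated replicate 2 or ATRA replicate 1), such as TNFAIP2 (1.01 ± 0.14). Of that list 2 fell (4 adjusted over the list alone, 1 without untreated replicate 1, ATRA replicate 1 or ATRA replicate 2), with TNF at -0.96 ± 0.18, and it did not shift (median -0.10, adjusted p = 0.724, adjusted p = 0.952 with an estimated correlation; 0.33 without untreated replicate 1, -0.21 without untreated replicate 2 and 0.00 without ATRA replicate 2). Of 9 leukocyte adhesion and homing genes, 4 rose (1 without untreated replicate 2 and 0 without ATRA replicate 1). ICAM1 led them at 1.28 ± 0.35, or 1.95 without untreated replicate 1, and did not pass without untreated replicate 2 (0.60) or ATRA replicate 1. The median was 0.29 (adjusted p = 0.0228, adjusted p = 0.64 with an estimated correlation; 0.49 without untreated replicate 1 and 0.44 without untreated replicate 2). In limma's test 604 genes passed, 437 higher and 167 lower. That count was 251 without untreated replicate 1, 244 without untreated replicate 2 and 165 without ATRA replicate 1.

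By 12 h of ATRA, CD38 was 23.4-fold higher (4.55 ± 0.18), and CHRNA6, a nicotinic acetylcholine receptor subunit, was 20.6-fold higher (4.36 ± 0.18). The integrin subunits ITGAX (CD11c, 2.04 ± 0.29) and ITGAM (CD11b, 1.92 ± 0.22) rose, as did the Src-family kinase FGR (2.96 ± 0.13). The glutamine transporter SLC38A1 (-1.58 ± 0.26) and the cystine transporter SLC7A11 (-1.38 ± 0.26) fell. The transcription factor BCL11A fell as well (-1.44 ± 0.14). Of 10 retinoid genes, 8 rose, with DHRS3 at 3.87 ± 0.14. Their median was 1.27 (adjusted p = 2.89e-09, adjusted p = 0.00426 with an estimated correlation). Of 11 phagocyte oxidase and myeloid integrin genes, 5 rose (3 without untreated replicate 2 or ATRA replicate 1). The median was 0.41 (adjusted p = 2.61e-04, adjusted p = 0.406 with an estimated correlation; 0.68 without untreated replicate 1, 0.08 without untreated replicate 2, 0.22 without ATRA replicate 1 and 0.67 without ATRA replicate 2). Of 11 granulocyte maturation genes, 5 rose (3 without ATRA replicate 1), with LRG1 at 2.04 ± 0.17 and the G-CSF receptor CSF3R at 1.18 ± 0.20. Their median was 0.29 (adjusted p = 6.43e-04, adjusted p = 0.029 with an estimated correlation; 0.15 without ATRA replicate 2). The granulocyte list holds 24 genes, and LTF, LCN2, MMP8 and MMP9 are among those not tested. Of 23 interferon response genes, 13 rose (5 without untreated replicate 2 or ATRA replicate 1), with IFI6 at 1.38 ± 0.25 and IRF1 at 1.19 ± 0.17. The median was 0.49 (adjusted p = 1.75e-05, adjusted p = 0.406 with an estimated correlation). Of 23 ATF4 targets and amino acid supply genes, 16 fell (21 adjusted over the list alone, 7 without untreated replicate 2 and 5 without ATRA replicate 1), with CHAC1, a glutathione-degrading enzyme, at -1.22 ± 0.16. Their median was -0.67 (adjusted p = 1.02e-06, adjusted p = 0.406 with an estimated correlation). Of 26 MYC and ribosome biogenesis genes, 23 fell (9 without untreated replicate 1 or 2 and 0 without ATRA replicate 1). LYAR led them at -1.18 ± 0.25 and did not pass without ATRA replicate 1. The median was -0.83 (adjusted p = 1.38e-08, adjusted p = 0.64 with an estimated correlation; -0.49 without ATRA replicate 1). Of 18 nucleotide synthesis genes, 13 fell (15 adjusted over the list alone, 8 without untreated replicate 1, 2 without untreated replicate 2 and 0 without ATRA replicate 1). Their median was -0.55 (adjusted p = 6.75e-06, adjusted p = 0.64 with an estimated correlation). On these arrays 133 small nucleolar and small nuclear RNAs had a median of 0.90, with 72 higher and 3 lower (0.68 to 1.1, with 9 to 76 higher and 0 to 4 lower, without 1 array). Altogether 3002 genes passed, 1433 higher and 1569 lower. The number was 1798 without untreated replicate 1, 800 without untreated replicate 2 and 570 without ATRA replicate 1. The split turned as well, since 63.5% were higher without untreated replicate 1, 62.6% without untreated replicate 2 and 76.8% without ATRA replicate 1, against 47.7% on all arrays and 40.2% without ATRA replicate 2.

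At 24 h CHRNA6 was 48.6-fold higher with ATRA (5.60 ± 0.18), CD38 33.4-fold (5.06 ± 0.18) and SPP1, the secreted phosphoprotein osteopontin, 19.8-fold (4.30 ± 0.61). ITGAM rose by 2.78 ± 0.22. CTSG, the neutrophil protease cathepsin G, fell (-2.19 ± 0.27), as did SLC7A5, a transporter of large neutral amino acids (-2.15 ± 0.29). Of 11 primary granule proteins, 3 rose, led by BPI, a bactericidal protein (3.84 ± 0.25). From the same list 6 fell (3 without untreated replicate 2 or ATRA replicate 1), including neutrophil elastase, ELANE (-1.13 ± 0.24), and the list did not shift (median -0.54, adjusted p = 0.392, adjusted p = 0.874 with an estimated correlation; -0.22 without ATRA replicate 1 and -0.85 without ATRA replicate 2). Of 10 measured retinoid genes, 8 rose, with TGM2 at 3.69 ± 0.33. The median was 1.59 (adjusted p = 4.51e-11, adjusted p = 0.00217 with an estimated correlation). Of 11 phagocyte oxidase and integrin genes, 6 rose. Their median was 0.50 (adjusted p = 8.01e-06, adjusted p = 0.196 with an estimated correlation). Of 11 granulocyte genes, 5 rose (3 without untreated replicate 2 or ATRA replicate 1), while S100A8, a calcium-binding alarmin, fell (-0.89 ± 0.15). The median was 0.31 (adjusted p = 0.0167, adjusted p = 0.153 with an estimated correlation; 0.13 without ATRA replicate 1). Of 11 monocyte and macrophage genes, 6 rose, with CD68 at 1.40 ± 0.14, while LYZ, lysozyme, fell (-0.96 ± 0.17). Their median was 0.67 (adjusted p = 0.0343, adjusted p = 0.358 with an estimated correlation). Of 23 interferon response genes, 16 rose, with OAS1, an RNA sensor, at 1.64 ± 0.23. The median was 0.79 (adjusted p = 6.14e-10, adjusted p = 0.153 with an estimated correlation). Of 23 ATF4 targets, 20 fell, with PSAT1 of serine synthesis at -1.59 ± 0.19. Their median was -1.13 (adjusted p = 4.51e-11, adjusted p = 0.153 with an estimated correlation). Of 34 DNA replication genes, 26 fell (29 adjusted over the list alone, 15 without untreated replicate 2 and 7 without ATRA replicate 1), with the phosphatase CDC25A at -1.58 ± 0.26. The median was -0.66 (adjusted p = 1.47e-10, adjusted p = 0.358 with an estimated correlation). Of 26 MYC and ribosome biogenesis genes, 23 fell (24 adjusted over the list alone, 14 without untreated replicate 1 or 2 and 3 without ATRA replicate 1), with POLR1A at -1.16 ± 0.25. Their median was -0.86 (adjusted p = 2.82e-09, adjusted p = 0.362 with an estimated correlation). In the BCL2 family BCL2A1 rose (1.46 ± 0.31) and BCL2 fell (-1.65 ± 0.21), and the 15 genes did not shift as a list (median 0.08, adjusted p = 0.842, adjusted p = 0.927 with an estimated correlation; -0.04 without untreated replicate 1 and 0.00 without ATRA replicate 2). Small RNAs had a median of -0.42, with 1 higher and 29 lower (-0.58 to -0.25, with 0 to 1 higher and 18 to 22 lower, without 1 array). Past the threshold were 3207 genes, 1423 higher and 1784 lower. The total became 1979 without untreated replicate 1, 1465 without untreated replicate 2 and 1318 without ATRA replicate 1. Of these totals 44.4% were higher on all arrays, 50.8% without untreated replicate 1 and 55.2% without ATRA replicate 1.

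**Figure D2:**
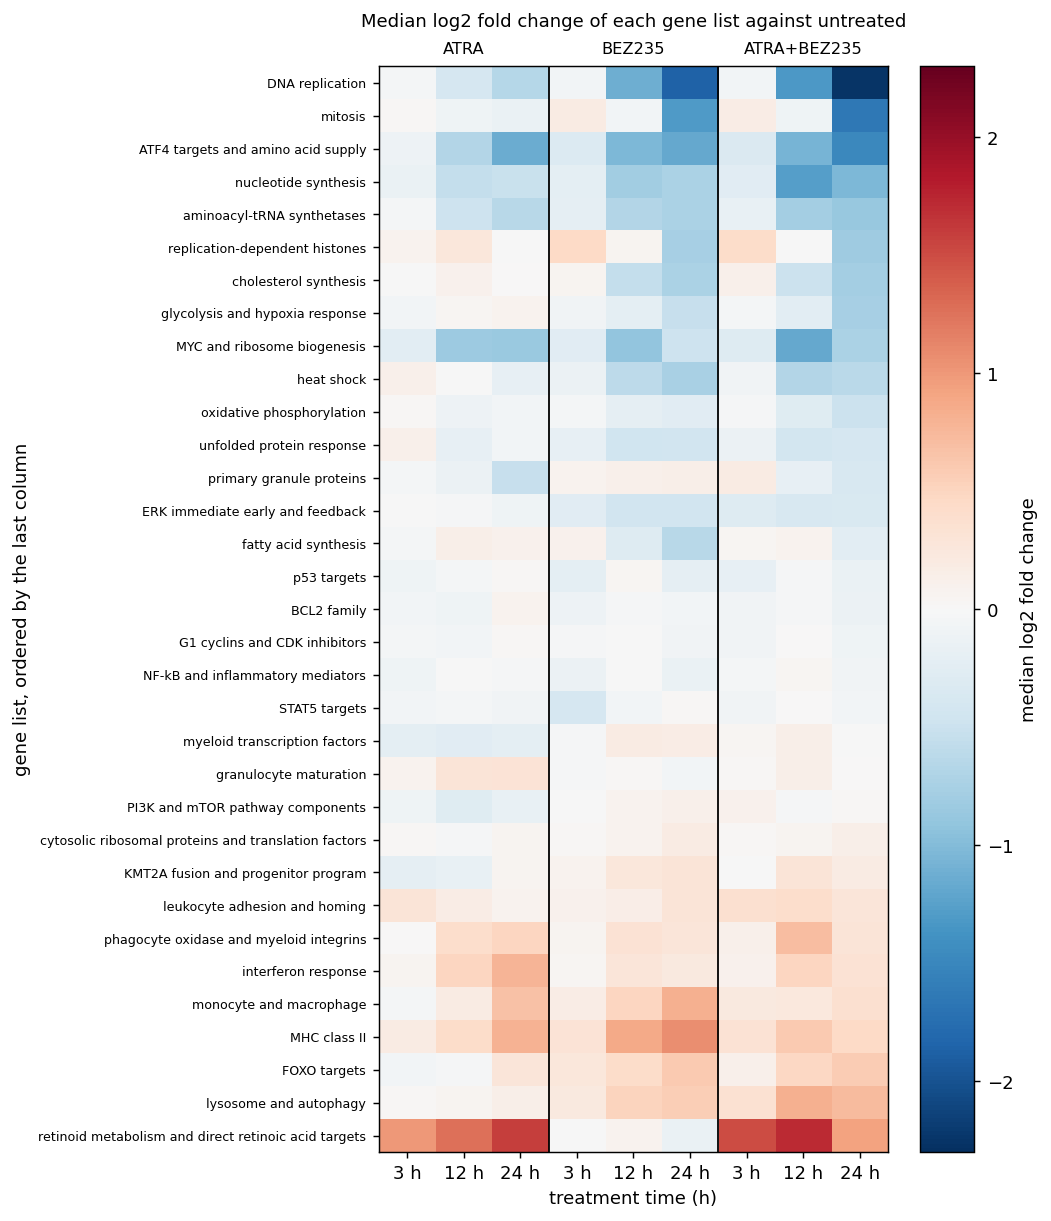
Median log2 fold change of the measured members of each gene list against untreated arrays of the same time, by drug and time (red higher, blue lower), ordered by the 24 h combination. DNA replication genes had medians of -1.85 with BEZ235 and -2.26 with both drugs at 24 h.

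The effect of BEZ235 alone was read in the same way. At 3 h ARRDC3, an alpha-arrestin (transcript cluster 8113073), was 13.8-fold higher (3.79 ± 0.30). KLHL24, a ubiquitin ligase adaptor, rose by 2.76 ± 0.25, the repressor HBP1 by 2.41 ± 0.27, and DDIT3, the stress transcription factor CHOP, by 2.18 ± 0.20. DUSP6, a phosphatase of ERK, fell (-1.78 ± 0.23), as did CDC25A (-1.51 ± 0.26). Of 20 FOXO targets, 7 rose (9 adjusted over the list alone, 4 without untreated replicate 2 or BEZ235 replicate 1), with cyclin G2, CCNG2, at 2.00 ± 0.18 and the ubiquitin ligase subunit FBXO32 at 1.36 ± 0.16. The median was 0.27 (adjusted p = 4.69e-05, adjusted p = 0.296 with an estimated correlation). Of 12 ERK immediate early and feedback genes, 4 fell (2 without untreated replicate 1 or BEZ235 replicate 1), with SPRY2, a feedback inhibitor, at -1.23 ± 0.17. Their median was -0.26 (adjusted p = 2.07e-04, adjusted p = 0.445 with an estimated correlation; -0.44 without untreated replicate 2). Of 10 STAT5 targets, 5 fell (6 adjusted over the list alone, 2 without untreated replicate 1 or BEZ235 replicate 1 and 3 without untreated replicate 2 or BEZ235 replicate 2), with the kinase PIM1 at -1.04 ± 0.16 and cyclin D2, CCND2, at -0.97 ± 0.13. The median was -0.38 (adjusted p = 0.00147, adjusted p = 0.445 with an estimated correlation). Of 16 p53 targets, 4 fell (7 adjusted over the list alone, 2 without untreated replicate 1, untreated replicate 2 or BEZ235 replicate 1), including AEN, a nuclease (-1.17 ± 0.21), while DDB2, a DNA damage binding protein, rose (0.80 ± 0.12). Their median was -0.23 (adjusted p = 0.0426, adjusted p = 0.445 with an estimated correlation). Of 23 ATF4 targets, 5 fell (9 adjusted over the list alone, 3 without untreated replicate 1, BEZ235 replicate 1 or BEZ235 replicate 2), with CHAC1 at -1.38 ± 0.16, although DDIT3, which belongs to the list, rose. The median was -0.32 (adjusted p = 0.00273, adjusted p = 0.574 with an estimated correlation). Of 25 lysosome and autophagy genes, 5 rose (1 without untreated replicate 2 or BEZ235 replicate 1), with FNIP1, a folliculin partner, at 0.87 ± 0.12. Their median was 0.23 (adjusted p = 0.00277, adjusted p = 0.574 with an estimated correlation; 0.14 without untreated replicate 2). Of 12 replication-dependent histone genes, 4 rose (9 adjusted over the list alone, 1 without untreated replicate 2 and 2 without BEZ235 replicate 1), with H4C2 at 1.0 ± 0.19. The median was 0.46 (adjusted p = 8.17e-05, adjusted p = 0.445 with an estimated correlation). The 133 small RNAs of these arrays had a median of 0.50, with 8 higher and 5 lower (0.30 to 0.65, with 0 to 18 higher and 2 to 3 lower, without 1 array). The test called 1296 genes, 888 higher and 408 lower. This became 670 without untreated replicate 1, 446 without untreated replicate 2, 368 without BEZ235 replicate 1 and 823 without BEZ235 replicate 2.

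At 12 h PSAT1, an enzyme of serine synthesis (transcript cluster 8156043), was 8.32-fold lower with BEZ235 (-3.06 ± 0.19). CDC25A (-2.64 ± 0.26) and CDC6, a licensing factor of replication origins (-2.63 ± 0.27), were low as well, and ARRDC3 (2.61 ± 0.30) and KLHL24 (2.57 ± 0.25) were high. Of 34 DNA replication genes, 30 fell (32 adjusted over the list alone), with cyclin E2, CCNE2, at -2.40 ± 0.22. Their median was -1.13 (adjusted p = 2.08e-18, adjusted p = 0.22 with an estimated correlation). Of 26 MYC and ribosome biogenesis genes, 24 fell, with LYAR at -1.93 ± 0.25. The median was -0.92 (adjusted p = 4.53e-09, adjusted p = 0.322 with an estimated correlation). Of 18 nucleotide synthesis genes, 15 fell, with CTPS1 at -1.78 ± 0.26. Their median was -0.79 (adjusted p = 1.36e-07, adjusted p = 0.296 with an estimated correlation). Of 23 ATF4 targets, 16 fell (17 adjusted over the list alone), with asparagine synthetase, ASNS, at -1.83 ± 0.20. The median was -1.03 (adjusted p = 4.1e-07, adjusted p = 0.22 with an estimated correlation). Of 11 aminoacyl-tRNA synthetases, 10 fell (11 adjusted over the list alone), with MARS1 at -1.44 ± 0.20. Their median was -0.67 (adjusted p = 1.67e-06, adjusted p = 0.22 with an estimated correlation). Of 9 heat shock genes, 8 fell (9 adjusted over the list alone), with the mitochondrial co-chaperonin HSPE1 at -1.43 ± 0.16. The median was -0.61 (adjusted p = 1.01e-06, adjusted p = 0.22 with an estimated correlation). Of 14 unfolded protein response genes, 7 fell (9 adjusted over the list alone), with HSPA5 (BiP) at -1.13 ± 0.13. Their median was -0.46 (adjusted p = 8.69e-05, adjusted p = 0.22 with an estimated correlation). Of 25 lysosome and autophagy genes, 16 rose, with WIPI1, an autophagosome protein, at 1.65 ± 0.22. The median was 0.52 (adjusted p = 2.86e-07, adjusted p = 0.22 with an estimated correlation). Of 20 FOXO targets, 10 rose (11 adjusted over the list alone). Their median was 0.43 (adjusted p = 2.96e-05, adjusted p = 0.22 with an estimated correlation). Of 11 monocyte and macrophage genes, 7 rose (4 without BEZ235 replicate 1), with the receptor CSF1R at 1.17 ± 0.19. The median was 0.49 (adjusted p = 0.00397, adjusted p = 0.22 with an estimated correlation). FLT3, the receptor kinase mutated in this line, rose by 0.59 ± 0.10. A total of 3958 genes passed, 1900 higher and 2058 lower, and it was 2428 without untreated replicate 2 and 2637 without BEZ235 replicate 1. The share higher was 48.0%, or 43.1 to 53.1% without 1 array.

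After 24 h of BEZ235, cyclin E2, CCNE2 (transcript cluster 8151871), was 13.9-fold lower (-3.80 ± 0.22). The checkpoint adaptor CLSPN was at -3.44 ± 0.26 (-2.38 on its other probe set), PSAT1 at -3.30 ± 0.19 and the helicase HELLS at -3.20 ± 0.13. KLHL24 (2.84 ± 0.25) and SIGLEC6, a sialic acid receptor (2.36 ± 0.12), were up. Of 34 DNA replication genes, 33 fell, with MCM10 at -2.79 ± 0.26. Their median was -1.85 (adjusted p = 5.17e-26, adjusted p = 0.112 with an estimated correlation). All 26 measured mitosis genes fell, with FOXM1 at -1.96 ± 0.22 and the checkpoint kinase BUB1B at -1.79 ± 0.11. The median was -1.30 (adjusted p = 1.31e-20, adjusted p = 0.00547 with an estimated correlation). Of 12 replication-dependent histones, 9 fell, with H2AC4 at -1.72 ± 0.32. Their median was -0.77 (adjusted p = 6.89e-05, adjusted p = 0.272 with an estimated correlation). Of 18 cholesterol synthesis genes, 14 fell (8 without untreated replicate 2 or BEZ235 replicate 1), with HMGCS1 at -1.47 ± 0.26. The median was -0.72 (adjusted p = 2.5e-05, adjusted p = 0.327 with an estimated correlation). Of 11 fatty acid synthesis genes, 7 fell, with FASN at -1.08 ± 0.18. Their median was -0.64 (adjusted p = 0.00494, adjusted p = 0.372 with an estimated correlation). Of 26 ribosomal proteins and translation factors, 8 rose (7 adjusted over the list alone, 5 without untreated replicate 1, BEZ235 replicate 1 or BEZ235 replicate 2 and 4 without untreated replicate 2), with RPL10A at 0.72 ± 0.13. For RPS9 (0.51 ± 0.11) the mean of its probe sets was -0.15 and not called. For RPL13 (0.37) that mean was -0.01 and not called either. The median was 0.19 (adjusted p = 5.64e-04, adjusted p = 0.112 with an estimated correlation). Of 20 FOXO targets, 14 rose, with TXNIP, a thioredoxin inhibitor, at 1.51 ± 0.21. Their median was 0.60 (adjusted p = 6.23e-06, adjusted p = 0.112 with an estimated correlation). Of 25 lysosome genes, 19 rose, with RRAGD, a GTPase of mTORC1 signalling, at 1.42 ± 0.17. The median was 0.56 (adjusted p = 6.96e-08, adjusted p = 0.192 with an estimated correlation). Of the 10 genes on the class II MHC list 5 were tested, the regulator CIITA among them. All 5 rose, with HLA-DPB1 at 1.60 ± 0.26 (0.73 on its other probe set). Their median was 1.07 (adjusted p = 9.48e-04, adjusted p = 0.192 with an estimated correlation). Of 18 PI3K and mTOR pathway components, 6 rose (2 without untreated replicate 1 or BEZ235 replicate 2), with DEPTOR, an mTOR inhibitor, at 1.86 ± 0.29. Of the same list 4 fell (5 adjusted over the list alone, 1 without untreated replicate 2 and 2 without BEZ235 replicate 1), with EIF4EBP1, a translation repressor, at -0.80 ± 0.15, and it did not shift (median 0.11, adjusted p = 0.501, adjusted p = 0.822 with an estimated correlation; 0.07 without untreated replicate 2 and 0.01 without BEZ235 replicate 1). The CDK inhibitor CDKN1B rose (0.93 ± 0.11) and the proliferation marker MKI67 fell (-1.30 ± 0.15). Leaving out any 1 array kept the total of 4221 genes, 2034 higher and 2187 lower, between 2932 and 3639, with 44.7 to 52.0% of them higher.

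Both drugs together were compared with untreated cells on the same untreated arrays that served the single drugs, so overlaps between these comparisons are not independent. At 3 h the combination raised ARRDC3 15.6-fold (3.96 ± 0.30), DHRS3 12.7-fold (3.66 ± 0.14) and CD38 12.4-fold (3.63 ± 0.18). MYC fell (-1.70 ± 0.16), as did MFSD2A, a lipid transporter (-1.86 ± 0.18), and TNF (-1.54 ± 0.18). Of 10 retinoid genes, 8 rose, with CYP26A1 at 3.53 ± 0.19. The median was 1.5 (adjusted p = 2.01e-10, adjusted p = 0.00252 with an estimated correlation). Of 25 lysosome and autophagy genes, 13 rose (14 adjusted over the list alone, 7 without untreated replicate 2 or combination replicate 1), with cathepsin D, CTSD, at 0.78 ± 0.12 and TFEB, a regulator of lysosomal genes, at 0.70 ± 0.12. Their median was 0.36 (adjusted p = 7.16e-06, adjusted p = 0.533 with an estimated correlation). Of 20 FOXO targets, 6 rose, with KLHL24 at 3.06 ± 0.25. The median was 0.12 (adjusted p = 0.0401, adjusted p = 0.662 with an estimated correlation; 0.19 without untreated replicate 1, 0.22 without combination replicate 1 and 0.04 without combination replicate 2). Of 9 adhesion and homing genes, 4 rose (5 adjusted over the list alone), with the chemokine receptor CXCR4 at 1.63 ± 0.18. Their median was 0.36 (adjusted p = 0.0105, adjusted p = 0.533 with an estimated correlation). Of 23 ATF4 targets, 7 fell (9 adjusted over the list alone, 3 without untreated replicate 1 or combination replicate 1 and 4 without untreated replicate 2), with CHAC1 at -1.58 ± 0.16, while DDIT3 of that list rose (3.05 ± 0.20). The median was -0.33 (adjusted p = 0.0196, adjusted p = 0.939 with an estimated correlation). Of 12 histone genes, 8 rose (2 without untreated replicate 2, combination replicate 1 or combination replicate 2). Their median was 0.42 (adjusted p = 0.00128, adjusted p = 0.662 with an estimated correlation). Small RNAs had a median of 0.16 on these arrays, with 3 higher and 11 lower (-0.15 to 0.34, with 0 to 4 higher and 5 to 17 lower, without 1 array). Of the 21 listed genes of the KMT2A fusion and progenitor program 10 were tested, without HOXA9 or HOXA10. Of these 10 genes, 3 rose, such as MEIS1 (0.68 ± 0.13) and RUNX2 (0.58 ± 0.12). Of that program 3 fell (4 adjusted over the list alone, 1 without untreated replicate 2, combination replicate 1 or combination replicate 2), such as GATA2 (-0.63 ± 0.11), and the list did not shift (median -0.01, adjusted p = 0.977, adjusted p = 0.985 with an estimated correlation; 0.02 without untreated replicate 1, -0.05 without untreated replicate 2, -0.01 without combination replicate 1 and 0.00 without combination replicate 2). Past the threshold were 2335 genes, 65.5% of them higher, or 78.5% when each array was shifted to a common median. The number passing was 1470 without untreated replicate 1, 1085 without untreated replicate 2, 1430 without combination replicate 1 and 1527 without combination replicate 2.

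By 12 h SELENOP, a selenium transport protein (transcript cluster 8111915), was 40.8-fold higher with both drugs (5.35 ± 0.19). It was followed by ITGA6 (4.91 ± 0.21), GPR34 (4.89 ± 0.48) and KCNE1, a potassium channel subunit (4.44 ± 0.34). The glutamine transporter SLC38A1 fell 14.0-fold (-3.81 ± 0.26), and PSAT1 (-3.33 ± 0.19) and UNG, a uracil DNA glycosylase (-2.93 ± 0.22), were low. Of 34 replication genes, 32 fell, with CCNE2 at -2.80 ± 0.22. The median was -1.32 (adjusted p = 5.14e-16, adjusted p = 0.274 with an estimated correlation). Of 18 nucleotide synthesis genes, 17 fell, with PRPS1 at -1.97 ± 0.20. Their median was -1.27 (adjusted p = 7.93e-09, adjusted p = 0.291 with an estimated correlation). Of 26 MYC and ribosome biogenesis genes, 24 fell, with LYAR at -2.17 ± 0.25. The median was -1.18 (adjusted p = 2.49e-09, adjusted p = 0.346 with an estimated correlation). Of 23 genes of the ATF4 and amino acid list, 19 fell (20 adjusted over the list alone), with SLC7A5 at -2.73 ± 0.29. Their median was -1.08 (adjusted p = 7.85e-08, adjusted p = 0.274 with an estimated correlation). Of 25 lysosome genes, 19 rose, with CTSD at 1.62 ± 0.12 and the sulfatase SGSH at 1.53 ± 0.10. The median was 0.82 (adjusted p = 5.56e-11, adjusted p = 0.263 with an estimated correlation). Of 10 retinoid genes, 8 rose, with CD38 at 4.88 ± 0.18. Their median was 1.71 (adjusted p = 2.92e-07, adjusted p = 0.0188 with an estimated correlation). Of 23 interferon response genes, 12 rose, with PSMB9, an immunoproteasome subunit, at 0.99 ± 0.16. The median was 0.50 (adjusted p = 0.00121, adjusted p = 0.387 with an estimated correlation). Of 11 phagocyte genes, 6 rose, with FGR at 3.33 ± 0.13. Their median was 0.70 (adjusted p = 0.00229, adjusted p = 0.344 with an estimated correlation; 0.41 without untreated replicate 2). Of 18 cholesterol synthesis genes, 10 fell (5 without untreated replicate 2), with EBP at -1.21 ± 0.12. The median was -0.49 (adjusted p = 0.0322, adjusted p = 0.676 with an estimated correlation). Of 4790 genes past the threshold 2123 were higher and 2667 lower, and the range without 1 array was 3455 to 4046.

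At 24 h SELENOP was 79.5-fold higher with both drugs (6.31 ± 0.19) and CD38 32.2-fold (5.01 ± 0.18), while CCNE2 was 17.1-fold lower (-4.10 ± 0.22). Of 34 replication genes, 33 fell, with MCM6 at -2.95 ± 0.13. Their median was -2.26 (adjusted p = 6.75e-23, adjusted p = 0.167 with an estimated correlation). All 26 mitosis genes fell, with the kinesin KIF20A at -2.10 ± 0.15. The median was -1.64 (adjusted p = 4.51e-19, adjusted p = 0.0077 with an estimated correlation). Of 23 genes of the ATF4 and amino acid list, 20 fell, with ALDH1L2, a mitochondrial folate enzyme, at -3.26 ± 0.23. Their median was -1.48 (adjusted p = 1.6e-07, adjusted p = 0.21 with an estimated correlation). Of 24 glycolysis and hypoxia response genes, 18 fell, with hexokinase 2, HK2, at -1.58 ± 0.16. The median was -0.76 (adjusted p = 5.16e-04, adjusted p = 0.328 with an estimated correlation). Of 15 oxidative phosphorylation genes, 10 fell (11 adjusted over the list alone), with SDHA at -0.92 ± 0.16. Their median was -0.50 (adjusted p = 0.0116, adjusted p = 0.245 with an estimated correlation). Of 25 lysosome genes, 18 rose (20 adjusted over the list alone), with CTSD at 2.06 ± 0.12 and PSAP, prosaposin, at 1.48 ± 0.12. The median was 0.73 (adjusted p = 1.63e-11, adjusted p = 0.161 with an estimated correlation). Of 10 measured retinoid genes, 6 rose, with DHRS3 at 3.88 ± 0.14. Their median was 0.92 (adjusted p = 7.68e-06, adjusted p = 0.0237 with an estimated correlation). CD68 rose by 2.23 ± 0.14, and S100A8 (-1.83 ± 0.15) and RNASE2, an eosinophil and neutrophil ribonuclease (-1.72 ± 0.15), fell. Of 14 G1 cyclins and CDK inhibitors, 2 rose, with CDKN1B at 1.02 ± 0.11. In that list 4 fell, with RBL1, a pocket protein, at -1.62 ± 0.12, and it did not shift (median -0.09, adjusted p = 0.767, adjusted p = 0.896 with an estimated correlation; -0.17 without untreated replicate 1 and -0.15 without combination replicate 1). MPO, myeloperoxidase (0.06), and CEBPE, a granulocyte transcription factor (-0.04), did not pass. Of the 5033 genes past the threshold 34.2% were higher, against 44.4% after another quantile normalization. Without replicate 1 of the combination 45.0% of 4242 genes were higher, and every left-out array gave between 3781 and 4986.

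**Figure D3:**
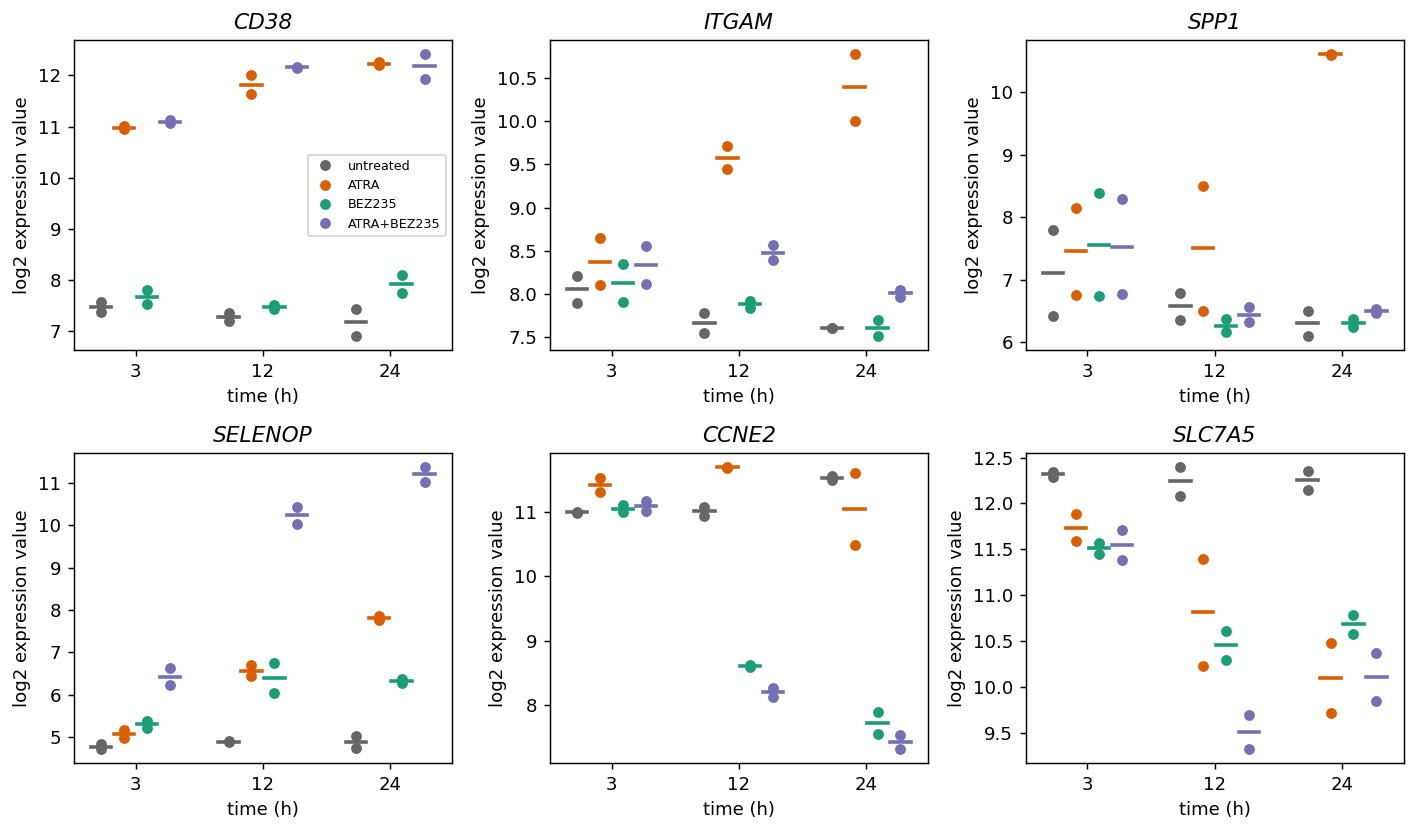
Log2 expression values of 6 genes on each of the 24 arrays by time (h) and drug, with a point per array and a line at the mean of the 2 replicates. At 24 h the log2 fold change of CD38 was 5.06 with ATRA and 5.01 with both, of SPP1 4.30 with ATRA and of SELENOP 6.31 with both.

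How ATRA acts in cells that also receive BEZ235 was read from the combination against BEZ235 alone. At 3 h HBEGF, a growth factor of the EGF family, was 16.9-fold higher (4.08 ± 0.25), CYP26A1 13.0-fold (3.70 ± 0.19) and DHRS3 12.8-fold (3.68 ± 0.14). TNFSF10, the death ligand TRAIL, fell (-1.40 ± 0.21). Of 10 measured retinoid genes, 7 rose (8 adjusted over the list alone). The median was 1.59 (adjusted p = 2.82e-27, adjusted p = 2.02e-05 with an estimated correlation). Of 415 genes past the threshold 334 were higher and 81 lower (250 without BEZ235 replicate 2 and 239 without combination replicate 1). At 12 h ITGA6 was 35.3-fold higher (5.14 ± 0.21), and SLC10A2, a bile acid transporter, fell (-2.28 ± 0.20). Of 10 measured retinoid genes, 7 rose (8 adjusted over the list alone). Their median was 1.57 (adjusted p = 1.18e-17, adjusted p = 1.98e-04 with an estimated correlation). Of 25 lysosome genes, 6 rose (7 adjusted over the list alone). The median was 0.19 (adjusted p = 8.43e-07, adjusted p = 0.46 with an estimated correlation). Of 836 genes 447 were higher and 389 lower (458 without BEZ235 replicate 2 and 445 without combination replicate 1), and the share higher of 53.5% was 52.4 to 66.4% without 1 array. At 24 h SELENOP was 29.2-fold higher (4.87 ± 0.19), CD38 19.2-fold (4.26 ± 0.18), and the protease CAPN2 fell (-2.00 ± 0.22). Of 10 measured retinoid genes, 7 rose. Their median was 1.07 (adjusted p = 1.12e-15, adjusted p = 3.6e-04 with an estimated correlation). Of 11 granulocyte genes, 3 rose (4 adjusted over the list alone). The median was 0.12 (adjusted p = 0.00241, adjusted p = 0.0467 with an estimated correlation; 0.21 without BEZ235 replicate 2 and 0.19 without combination replicate 1). Of 26 mitosis genes, 12 fell (15 adjusted over the list alone, 5 without BEZ235 replicate 1 or combination replicate 1 and 6 without BEZ235 replicate 2). Their median was -0.36 (adjusted p = 1.16e-05, adjusted p = 0.185 with an estimated correlation). The count of 1093 genes, 319 higher and 774 lower, was 688 without BEZ235 replicate 1, 640 without combination replicate 1 and 2360 without combination replicate 2. Of these, 332 and 358 were higher without combination replicates 1 and 2.

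What BEZ235 adds to ATRA was read from the combination against ATRA alone. At 3 h ARRDC3 was 5.66-fold higher (2.5 ± 0.30), with KLHL24 at 1.90 ± 0.25 and THBS1, thrombospondin 1, at 1.91 ± 0.19, and CHAC1 fell (-1.39 ± 0.16). Of 20 FOXO targets, 6 rose (8 adjusted over the list alone). The median was 0.18 (adjusted p = 1.51e-06, adjusted p = 0.159 with an estimated correlation; 0.27 without ATRA replicate 2 or combination replicate 1). There were 533 genes past the threshold, 374 higher and 159 lower (272 without ATRA replicate 1, 150 without ATRA replicate 2, 221 without combination replicate 1 and 236 without combination replicate 2). At 12 h CCNE2 was 11.2-fold lower (-3.48 ± 0.22) and SELENOP 12.8-fold higher (3.67 ± 0.19). Of 34 replication genes, 30 fell (31 adjusted over the list alone). Their median was -0.91 (adjusted p = 5.78e-19, adjusted p = 0.242 with an estimated correlation). Of 25 lysosome genes, 21 rose (23 adjusted over the list alone), with SQSTM1, an autophagy receptor, at 1.27 ± 0.16. The median was 0.68 (adjusted p = 5.13e-13, adjusted p = 0.242 with an estimated correlation). Of the 21 listed genes of the KMT2A fusion and progenitor program 10 were tested, without HOXA9 or HOXA10. Of these 10 genes, 6 rose, with FLT3 at 0.51 ± 0.10. Their median was 0.50 (adjusted p = 0.0035, adjusted p = 0.277 with an estimated correlation). The count of 3200 genes, 1521 higher and 1679 lower, was 1849 without combination replicate 2, with 39.2 to 52.4% higher over the left-out arrays. At 24 h SPP1 was 17.2-fold lower (-4.10 ± 0.61) and the leukocyte receptor LILRA5 8.78-fold lower (-3.13 ± 0.25), while MYO10, an unconventional myosin, rose (2.53 ± 0.21). All 26 mitosis genes fell. The median was -1.57 (adjusted p = 6.51e-24, adjusted p = 0.00262 with an estimated correlation). Of 24 glycolysis and hypoxia response genes, 18 fell (19 adjusted over the list alone), with ENO2, an enolase, at -1.78 ± 0.33. Their median was -0.82 (adjusted p = 1.22e-07, adjusted p = 0.23 with an estimated correlation). Of 23 interferon response genes, 10 fell (11 adjusted over the list alone), with IFI6 at -2.05 ± 0.25. The median was -0.23 (adjusted p = 0.028, adjusted p = 0.674 with an estimated correlation; -0.55 without ATRA replicate 2). Without 1 array the 3456 genes, 1150 higher and 2306 lower, became 2329 to 3490. The split followed the combination arrays, with 1704 higher and 1786 lower without replicate 1 and 623 and 2513 without replicate 2.

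The effects of each drug alone and on top of the other share no array and can be set side by side. ATRA raised 437, 1433 and 1423 genes alone at 3, 12 and 24 h. Of these 212, 317 and 241 also rose on top of BEZ235, where 12.5, 54.8 and 38.8 would be shared if calls were independent. It lowered 167, 1569 and 1784 genes, of which 41, 203 and 270 also fell on top, against 1.2, 52.2 and 118.1. BEZ235 raised 223, 974 and 772 genes both alone and on top of ATRA, against 28.4, 247.2 and 200.1. It lowered 125, 1066 and 1361 in both settings, against 5.5, 295.6 and 431.5. Genes are correlated, so these expected counts carry no test. Of the genes ATRA raised alone, 93.6, 77.9 and 59.4% had the same sign on top of BEZ235 at 3, 12 and 24 h, and their medians went from 0.69, 0.67 and 0.61 alone to 0.5, 0.15 and 0.06 on top. Of those it lowered, 96.4, 89.2 and 90.3% kept their sign, with medians of -0.64, -0.54 and -0.58 alone and -0.35, -0.19 and -0.25 on top. For BEZ235 these shares were 95.8, 88.3 and 79.4% of the raised genes and 97.1, 94.7 and 93.8% of the lowered ones. The genes were chosen on the effect alone, which by itself makes the median on top smaller.

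Whether both drugs together departed from the sum of the single effects on the log2 scale was tested as an interaction within each time. At 3 h TRIM31, a ubiquitin ligase, passed (1.08 ± 0.17, adjusted p = 0.0474), and 565 genes had an unadjusted p under 0.05 in limma. This count of 1 was 0 without untreated replicate 2, BEZ235 replicate 1, combination replicate 1 or combination replicate 2 and 3 without ATRA replicate 1. How many genes pass at each time depends on the settings of the fit, and a gene that did not pass is not shown to be additive. With the replicate number as a block more genes passed at each time, as given with the other settings below. At 12 h SELENOP lay above the sum (2.17 ± 0.28), as did MYO10 (1.92 ± 0.30), and LILRA5 (-2.36 ± 0.35) and RNASE2 (-1.47 ± 0.21) lay below it. The lowest value was in LY96, a TLR4 partner (-2.84 ± 0.60), followed by the small nucleolar RNA SNORD116-26 (-2.56 ± 0.57), 1 of 5 small RNAs below the sum (0 to 33 without 1 array). Neither passed without either untreated replicate, ATRA replicate 1, BEZ235 replicate 1 or combination replicate 2. In the MYC and ribosome biogenesis list 0 of 26 genes passed. Their median was 0.57 (adjusted p = 3.2e-06, adjusted p = 0.592 with an estimated correlation; 0.27 without ATRA replicate 1 and 0.89 without ATRA replicate 2). In all 110 genes passed, 35 above and 75 below. The count was 56 without untreated replicate 1, 13 without untreated replicate 2, 18 without ATRA replicate 1, 636 without ATRA replicate 2, 15 without BEZ235 replicate 1 and 16 without combination replicate 2. Without ATRA replicate 1 it split into 9 above and 9 below, and the share above was 20 to 50% over the left-out arrays.

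At 24 h several genes that ATRA alone raised lay below the sum. ITGAM, 2.78 ± 0.22 with ATRA alone, was at 0.40 ± 0.22 with both drugs, where it did not pass, and its interaction was -2.38 ± 0.32. LILRA5 was below the sum too (-2.94 ± 0.35), as were the scavenger receptor CD36 (-2.42 ± 0.33) and AOAH, an enzyme that deacylates lipopolysaccharide (-2.55 ± 0.41). SPP1 was lowest (-4.10 ± 0.87) and did not pass without ATRA replicate 1, and CYP26A1 was at -1.42 ± 0.26. Above the sum lay SELENOP (1.94 ± 0.28), MYO10 (1.77 ± 0.30), CHAC1 (1.76 ± 0.23) and SLC3A2, a subunit of amino acid transporters (1.20 ± 0.20). Of 23 interferon response genes, 11 lay below (12 adjusted over the list alone, 4 without untreated replicate 1 or 2, 2 without ATRA replicate 1 and 6 without BEZ235 replicate 2 or combination replicate 1), with RSAD2, an antiviral enzyme, at -1.48 ± 0.25. The median was -0.68 (adjusted p = 1.14e-07, adjusted p = 0.272 with an estimated correlation). Of 5 class II MHC genes, 4 lay below (5 adjusted over the list alone, 2 without untreated replicate 2 or ATRA replicate 1), with HLA-DPA1 at -1.75 ± 0.29. Their median was -1.0 (adjusted p = 8.28e-06, adjusted p = 0.245 with an estimated correlation). Of 11 monocyte and macrophage genes, 5 lay below (7 adjusted over the list alone, 2 without ATRA replicate 1), with the Fc receptor FCGR2A at -1.34 ± 0.25. The median was -0.96 (adjusted p = 0.00104, adjusted p = 0.245 with an estimated correlation). Of 20 FOXO targets, 6 lay below (9 adjusted over the list alone, 3 without untreated replicate 2, 2 without ATRA replicate 1 and 10 without ATRA replicate 2), with TNFSF10 at -2.24 ± 0.29. Their median was -0.58 (adjusted p = 0.00131, adjusted p = 0.272 with an estimated correlation; -0.34 without ATRA replicate 1). Of 23 genes of the ATF4 and amino acid list, 5 lay above (11 adjusted over the list alone, 3 without untreated replicate 1 or BEZ235 replicate 2 and 2 without untreated replicate 2 or ATRA replicate 1). The median was 0.71 (adjusted p = 4.56e-08, adjusted p = 0.272 with an estimated correlation; 0.43 without ATRA replicate 1). Of 660 genes 85 lay above and 575 below, and the count was 356 without untreated replicate 1, 175 without untreated replicate 2, 160 without ATRA replicate 1, 378 without BEZ235 replicate 1 and 1026 without combination replicate 2. Leaving out combination replicate 1 gave 598 genes, 206 above and 392 below.

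**Figure D4:**
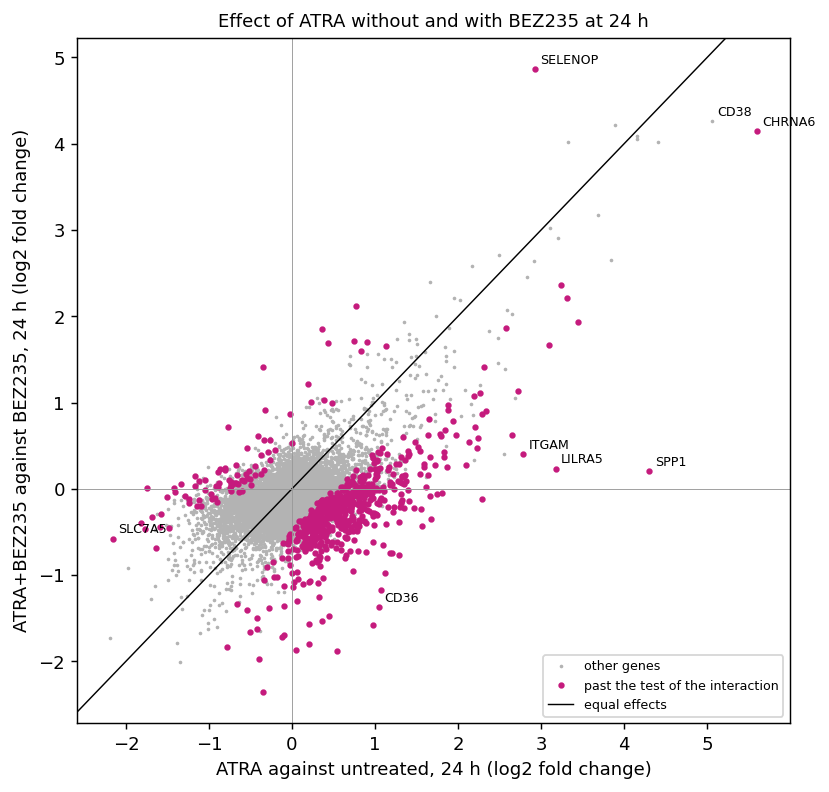
Log2 fold change by ATRA at 24 h without BEZ235 (x axis) and on top of BEZ235 (y axis), with a point per gene, the 660 genes past the test of the interaction in magenta and a line of equal effects. Of these genes 575 lie below the line and 85 above it.

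How the effects changed between 3 and 24 h was tested as a difference of effects. The ATRA effect moved upward for CHRNA6 (3.21 ± 0.26), BPI (3.16 ± 0.36) and ITGAM (2.46 ± 0.32) and downward for ID1 (-2.17 ± 0.21) and CTSG (-2.15 ± 0.38). There 204 genes differed, 120 upward and 84 downward. This was 86 without untreated 3 h replicate 1, 133 without untreated 3 h replicate 2, 91 without untreated 24 h replicate 1, 94 without untreated 24 h replicate 2, 73 without ATRA 3 h replicate 2 or ATRA 24 h replicate 1 and 463 without ATRA 24 h replicate 2, with 55.9 to 77.6% upward against 58.8% on all arrays. The BEZ235 effect moved downward for FAM111B, a replication-associated protease (-3.88 ± 0.27), CCNE2 (-3.85 ± 0.31) and HELLS (-3.10 ± 0.18), and upward for MYC (1.21 ± 0.23). Of 34 DNA replication genes, 33 moved downward. Their median was -1.72 (adjusted p = 6.73e-34, adjusted p = 0.126 with an estimated correlation). All 26 mitosis genes moved downward (median -1.48, adjusted p = 9.14e-34, adjusted p = 5.28e-04 with an estimated correlation). In total 1627 genes differed, 587 upward and 1040 downward (1077 without untreated 3 h replicate 1). The combination's effect moved upward for SELENOP (4.66 ± 0.28) and downward for CCNE2 (-4.20 ± 0.31) and CYP26A1 (-2.78 ± 0.26). All 26 mitosis genes moved downward here too (median -1.97, adjusted p = 6.34e-29, adjusted p = 0.00113 with an estimated correlation). Here 2413 genes differed, 545 upward and 1868 downward, or 761 and 1538 without combination 24 h replicate 1 and 922 and 1564 after another quantile normalization, which moved the median of all genes by 0.10.

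Untreated cells were compared over time as the background. Between 3 and 12 h limma called 0 genes, with 872 at an unadjusted p under 0.05, and 7 genes without replicate 2 at 3 h. Between 3 and 24 h COX7B, a subunit of cytochrome c oxidase, rose (1.70 ± 0.21). ARRDC4, an alpha-arrestin, fell (-1.60 ± 0.24) and did not pass without 3 h replicate 1. Of the 133 small RNAs 15 rose, or 0 to 3 without 1 array, with a class median of 0.65 (0.46 to 0.86). The 691 genes, 600 higher and 91 lower, became 24 without untreated 3 h replicate 1, 184 without untreated 3 h replicate 2, 5 without untreated 24 h replicate 1 and 405 without untreated 24 h replicate 2, with 80.0 to 100% of them higher.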

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

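Some tests were chosen only after the result was seen, namely that of noise in the 24 h ATRA arrays and the permutation of the small RNAs. The difference between the effects of the drugs alone and together, the difference of effects between 3 and 24 h, and signals of probe sets outside the gene comparisons singled these results out.

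The interaction at 24 h called 660 genes, 575 of them below the sum of the single effects (549 of 662 after another quantile normalization), with SPP1 at -4.10 (not past the threshold without ATRA replicate 1) and SELENOP at 1.94 above it. The count was 356 without untreated replicate 1, 175 without untreated replicate 2, 160 without ATRA replicate 1, 378 without BEZ235 replicate 1 and 1026 without combination replicate 2, and 392 of 598 lay below without combination replicate 1, whose values had the narrowest range. For genes that ATRA raised at 12 h, the tables argue against that array as the cause. The median 24 h interaction of these 1433 genes was -0.45 without it. Among all called genes the excess below the sum was smaller without that array, so part of that excess can come from it. The tables also argue against a ceiling at the top of the signal. Of the 575 genes, 1.91% had a summed level above the 99th percentile of 13.4. Compression of fold changes at lower levels was not tested. Noise in the 24 h ATRA arrays is argued against as well. Genes chosen on the 12 h arrays had a median of -0.41 (-0.45 to -0.38 without 1 array). Overlap of the single responses was not decided. The 853 genes that ATRA but not BEZ235 raised at 12 h had -0.29 (-0.35 to -0.24), which met the limit set beforehand as counting against overlap. For the 580 raised by both it was -0.58. A gene not called with BEZ235 at 12 h can respond to it at 24 h, so meeting that limit does not decide the question. Of the 575 genes, 262 were called higher with each drug alone at 24 h. A biological difference between the treatments stays open as untested, since effects of the inhibitor on survival, cell number or the uptake of ATRA were not measured here and assays of these in the 4 treatments would be needed to decide it.

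Small nucleolar and nuclear RNAs shifted between groups as a class of 133 genes, from a median of 0.90 with ATRA at 12 h (0.68 to 1.1 without 1 array) to -0.42 with ATRA at 24 h (-0.58 to -0.25). With BEZ235 the medians were 0.43 at 12 h and -0.17 at 24 h, and with both drugs 0.38 and -0.41. On untreated arrays the median rose by 0.65 from 3 to 24 h. Replicates of a group differed by up to 1.12 in the class median. Over 100000 permutations of the arrays across the 12 groups, the ratio of the spread between groups to that within (1.42) was reached with a permutation p of 0.22. Recovery of small RNAs that varies from array to array and an effect of the drugs cannot be told apart for these genes, because 2 arrays per group leave the class median too uncertain. The small RNAs named at 12 h in the interaction and RNU5D-1 belong to this class.

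At 12 h the interaction called 110 genes (56 and 13 without untreated replicates 1 and 2, 18 and 636 without ATRA replicates 1 and 2, 15 without BEZ235 replicate 1, 16 without combination replicate 2), with SELENOP at 2.17 and LY96 at -2.84, the latter lost without either untreated array, ATRA replicate 1, BEZ235 replicate 1 or combination replicate 2. At 3 h it called 1 gene, TRIM31 at 1.08, lost without untreated replicate 2, ATRA replicate 1, BEZ235 replicate 1 or either combination array, and the number was 0 to 3 over the left-out arrays. The interaction counts at 3, 12 and 24 h come from the fit without a block. With the replicate number as a block more genes were called at each of these times. Between 3 and 24 h the ATRA effect differed in 204 genes, with SPP1 at 3.96 and ID1 at -2.17. That number was 86 and 133 without untreated 3 h replicates 1 and 2, 91 and 94 without untreated 24 h replicates 1 and 2, 73 without ATRA 3 h replicate 2 or ATRA 24 h replicate 1, and 463 without ATRA 24 h replicate 2. The SPP1 difference did not pass without untreated 3 h replicate 1, either untreated 24 h array, ATRA 3 h replicate 2 or ATRA 24 h replicate 1. The BEZ235 effect differed in 1627 genes (1077 without untreated 3 h replicate 1), with SLC1A3, a glutamate transporter, at 2.39 and RNU5D-1 at -4.62. The effect of the combination differed in 2413 genes, with SELENOP at 4.66 and CCNE2 at -4.20.

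Of 5673 probe sets without a single gene name, 17, 461 and 662 passed against untreated cells with ATRA at 3, 12 and 24 h. With BEZ235 these numbers were 71, 639 and 706, and with both drugs 206, 881 and 1414.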

How the results depend on the processing

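Of the settings in this part, the tests with protein-coding genes alone and with an estimated correlation and a block were chosen only after the results were seen. Of the 594 list tests in the 18 drug and interaction comparisons, none called turned direction under the filters, the scalings, the mean of a gene's probe sets, the arrays of a time point, the blocks, fry or the estimated correlation. The trend and robust prior, protein-coding genes and left-out arrays were not run for the list tests, and the cause of each change given here was not tested. With the replicate number as a replicate block, or as a block within a time point, counts rose. Labels do not say what a replicate number stands for. Deviations of same-numbered arrays correlated by more than 0.1 in 58 of 66 pairs of groups (median 0.31, lowest -0.04, highest 0.69), by 0.20 to 0.61 among the 3 h groups, 0.44 to 0.69 at 12 h and -0.04 to 0.38 at 24 h, and 4034 genes differed between replicates 1 and 2. Every pair within 3 h and within 12 h exceeded 0.1, whereas not every pair at 24 h did. Same-numbered arrays thus share a structure, most clearly at 3 and 12 h, and its origin stays open. The block was kept as an alternative. The main fit leaves this structure in the residual spread, and its counts were lower than the blocked ones given next. Genes called under the block and under the block within a time point numbered 1329 and 1473 for ATRA at 3 h, 2306 and 2497 for BEZ235 at 3 h, 1081 and 1198 for the combination against ATRA at 3 h, 1313 and 1397 against BEZ235 at 12 h and 2116 and 2253 at 24 h. The interaction gave 15 and 28 at 3 h, 1035 and 1235 at 12 h and 1890 and 2066 at 24 h, and the effects at 24 h minus 3 h gave 1053 and 1197 for ATRA and 2511 and 2664 for BEZ235. Within a time point alone, the combination gave 3605 at 3 h and 3784 for its difference over time, and the block gave 39 genes for untreated 12 h and 1429 for untreated 24 h against 3 h. With only the arrays of a time point, ATRA at 24 h gave 2014, the combination against BEZ235 at 24 h 406, and the interaction 0, 40 and 216 at 3, 12 and 24 h, while only untreated arrays gave 1815 for 24 against 3 h. The 3 h interaction gave 0 with the stricter filter on dim genes, 2 with the trend and robust prior and 2 with protein-coding genes only. Untreated 12 against 3 h gave 1 with no filter on dim genes. Of 212 list calls at the preset correlation 14 were kept with an estimated correlation and 10 with that and the replicate block, and fry called 197, of which 150 were shared. RPS9 and RPL13 with BEZ235 at 24 h reversed to -0.146 and -0.009 with the mean of a gene's probe sets.

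Scaling moved the median of all genes by -0.07 to 0.10. Against untreated cells at 3 h, 1781 higher and 489 lower genes followed the shift to a common median for the combination, and at 24 h 2264 and 2832 followed another quantile normalization. The latter gave 176 and 76 for the ATRA effect over time.

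Without 1 array the number of genes ranged from 165 to 515 for ATRA at 3 h, 570 to 3712 at 12 h and 1318 to 2691 at 24 h. For BEZ235 it was 368 to 823, 2428 to 3045 and 2932 to 3639, and for the combination 1085 to 1527, 3455 to 4046 and 3781 to 4986. Against BEZ235 the combination gave 239 to 297, 445 to 626 and 640 to 2360, and against ATRA 150 to 272, 1849 to 2563 and 2329 to 3490. The interaction gave 0 to 3, 13 to 636 and 160 to 1026. Untreated cells gave 0 to 7 at 12 h and 5 to 405 at 24 h against 3 h, and the effects over time 73 to 463 for ATRA, 1077 to 1456 for BEZ235 and 1681 to 3031 for the combination. Each of these settings leaves a group with 1 array. None used a block, so part of these ranges can come from the structure that same-numbered arrays share, and this was not separated from the weight of a single array. Without ATRA replicate 1 the count was 570 at 12 h and 1318 at 24 h. Signal near the background of the arrays compresses fold changes, also for genes the filter kept, since it asks for signal above the median on only 2 of 24 arrays.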

Other observations

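Values in this part come from the planned comparisons, and setting them side by side was chosen after the results were seen. MYC, a driver of growth, followed different courses with the drugs. With ATRA it was at -1.27 ± 0.16 at 3 h and -0.96 ± 0.16 at 24 h. With BEZ235 it was at -0.71 ± 0.16 at 3 h (not passing without either untreated array or BEZ235 replicate 1) and 0.50 ± 0.16 at 24 h (not passing without either untreated array or BEZ235 replicate 2), and the difference between these times was 1.21 ± 0.23. CYP26A1, which degrades retinoic acid, was at 3.53 ± 0.19 with both drugs at 3 h, 1.94 ± 0.19 at 12 h and 0.75 ± 0.19 at 24 h, when its call was lost without untreated replicate 1. With ATRA alone it was at 2.10 ± 0.19, 1.49 ± 0.19 and 2.29 ± 0.19 at those times.

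TLR2, a receptor for bacterial lipopeptides, was at -0.98 ± 0.14 with ATRA at 3 h and 1.06 ± 0.14 with BEZ235 at 24 h, and on top of BEZ235 it was at -1.44 ± 0.14 at 12 h and -1.66 ± 0.14 at 24 h. DDIT4, an inhibitor of mTORC1, was at 1.93 ± 0.20 when ATRA was added to BEZ235 at 3 h and at -2.35 ± 0.20 with BEZ235 alone at 24 h. ATRA raised 253 and lowered 85 genes at all 3 times. BEZ235 raised 434 and lowered 227, and the combination raised 702 and lowered 429, on arrays of which the untreated ones are shared by the drugs.

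Genes listed as markers of other cell types were called in some comparisons, although all arrays are of a single cell line. Few listed markers were tested, namely 3 of 8 B-cell, 1 of 8 T-cell, 3 of 8 erythroid, 1 of 7 megakaryocyte and platelet, and 3 of 6 epithelial genes. Of the B-cell genes, CD79B (0.65) and CD79A (0.38, lost without either untreated array or ATRA replicate 1) rose with ATRA at 24 h and BLK (-0.07) did not pass. In the combination against ATRA at 24 h, CD79A fell (-0.41, lost without ATRA replicate 1 or combination replicate 1), as did CD79B (-0.39, lost without either ATRA array or combination replicate 2). The keratin KRT8 rose with both drugs at 12 h (0.60) and 24 h (0.61) and with BEZ235 at 24 h (0.48, lost without untreated replicate 1 or BEZ235 replicate 2). KRT18 rose with BEZ235 at 12 h (0.38, lost without any of the 4 arrays) and in the combination against ATRA at 24 h (0.47, lost without ATRA replicate 1 or combination replicate 2, and at 0.71 and 0.23 without combination replicates 1 and 2). With both drugs at 3 h the erythroid gene EPOR rose (0.56, lost without untreated or combination replicate 2) and the platelet gene GP9 fell (-0.36, lost without either untreated array or combination replicate 2, and at -0.57 and -0.15 without combination replicates 1 and 2). The EPOR effect differed by -0.71 between 3 and 24 h (lost without combination 24 h replicate 1). The T-cell kinase LCK was called in 0 of the 23 comparisons by limma.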
